A study of Drosophila melanogaster with 7 samples.

How the data were processed

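The material was chromatin from Kc167 cells, per the labels' protocols. Formaldehyde-fixed cells (1%) were stained with an antibody against phosphorylated histone H3 and with propidium iodide, and sorted into interphase and mitotic populations. Chromatin was then sonicated to 200 to 1000 bp and precipitated with antibodies against CP190, dCTCF, BEAF or Su(Hw), and libraries were selected for 200 to 300 bp on a gel. The CP190, BEAF and Su(Hw) antibodies were raised in rabbit and the dCTCF antibody was a mixture from guinea pig and rat. The H3 antibody used for sorting was detected with an anti-rabbit reagent and was present before the precipitation.

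Reads were aligned with Bowtie 0.12.5, per the submitters' processing notes. The authors deposited 1 list of peaks per library, with 5 columns: sequence name, start, end, a peak name and a score. The peak names begin with MACS, and the deposited score of each peak has a floor of 50 and many peaks tied at 3100 (534 in the interphase CP190 list), which is the range of the -10 times log10 p that MACS writes. No label or header states the meaning of the score, the version of the peak caller, its threshold or whether a control library was used, and these are not given in the sources used here. A score depends on the depth of its library as well as on the strength of binding, so scores were used to rank or filter peaks within 1 list. Where the scores of a site in several lists are printed, they do not compare the strength of binding between lists. A score of 3100 may be a ceiling, so the order among peaks at or above it is not an order of strength, and this bears on which peaks are named as the highest scoring. The genome build is not given in the sources used here. Sequence names such as 2LHet and Uextra are those of Drosophila genome release 5, and positions are given as in the files, 1-based. The gene table used here is of release 6, and positions were not carried between releases. Peaks were therefore not assigned to genes, exons, introns or UTRs, and the planned analyses of start site distance, gene lists and motifs were not run.

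Each peak list was compared with each other list by overlap of at least 1 bp. Shares were given with 95% Wilson intervals and differences of shares with 95% Newcombe intervals, which cover counting error only. For each pair, the peaks of the first list were placed at random within their chromosomes 1000 times, keeping their widths, and the median share is given as the chance level. The highest peak end on each sequence stood for its length. Random placement takes no account of the tendency of peaks of any antibody to lie in open chromatin. Peaks were also divided into quintiles and deciles of the score within a list, and by the presence of an interphase peak of another protein. Analyses by score or partner were made on the main arms, a choice made after the share of peaks on Uextra was seen; quintiles over the whole lists had been fixed for the differences with and without CP190, and these are given too. The comparisons with equal numbers of interphase peaks and of mitotic CP190 at strong dCTCF sites were also added after the data were seen. The calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and the figures matplotlib 3.10.9. Lists were simulated by shifting real peaks by less than the narrowest peak width, and all 16155 shared peaks were found. That shift fixed their overlap in advance, so this checks the code alone. A further 330 unshared peaks were hit by a shifted neighbour. On the real lists the overlap counts were equal to those of bedtools 2.31.1 in 98 of 98 list pairs and rules.

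Groups were taken from the sample titles, 1 library per group, so no test between groups was possible, replicates could not be left out in turn and no p-value was computed. The interphase and mitotic lists of CP190, dCTCF and BEAF were compared, and the overlap of dCTCF, BEAF and Su(Hw) with CP190 in each phase. An interphase list for Su(Hw) was not analysed here. Before the data were examined, these alternatives were fixed: a reciprocal overlap of 50%, a score of at least 100 in each list, equal numbers of the highest scoring peaks, 400 bp around each midpoint, and the main arms only. The rule for named peaks was also fixed then: for each of CP190, dCTCF and BEAF, the 8 highest scoring peaks on the main arms among those retained, those called in interphase alone and those called in mitosis alone, and the 8 highest scoring Su(Hw) peaks. From these, examples are given in the text. Read numbers per library were not used here, so the depth behind each list is unknown.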

Results

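The data are 7 lists of chromatin immunoprecipitation sequencing (ChIP-seq) peaks for 4 insulator proteins in Kc167 cells, an established embryonic cell line of Drosophila melanogaster. Insulator proteins bind sites that separate or connect regulatory domains of chromatin. CP190, a zinc-finger protein recruited by other insulator proteins, dCTCF, the fly homolog of CTCF, and BEAF, the boundary element-associated factor, were each profiled in interphase and in mitosis. Su(Hw), the zinc-finger protein that binds the gypsy insulator, was analysed here in mitosis. Fixed cells had been sorted into both populations by staining for phosphorylated histone H3 and for DNA, and the design sets interphase against mitosis for each protein.

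Each group was 1 library, so no difference has a replicate check and no p-value is given. Peaks are sites within a library, not replicates. Intervals are 95% Wilson intervals of a share and cover counting error only. The lists give no read numbers, so the depth behind them is unknown and a site missing from a list was not called at that depth, which does not show that the protein was absent. A peak is called retained below when an interphase peak overlapped a mitotic peak of the same protein by at least 1 bp. Positions are those of the authors' lists, whose sequence names are those of Drosophila genome release 5, and peaks were not assigned to genes. Scores are the authors' and may be capped near 3100, so the order among the strongest named peaks is not an order of strength. Since depth is unknown, a lower score of a site in mitosis than in interphase does not show weaker binding.

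The interphase lists held 11470 CP190 peaks, 7980 BEAF peaks and 3962 dCTCF peaks. The mitotic lists held 5608 CP190 peaks, 3325 BEAF peaks, 6030 dCTCF peaks and 1829 Su(Hw) peaks. From interphase to mitosis the number of CP190 peaks fell by 5862 and that of BEAF fell by 4655, whereas dCTCF had 2068 more. The direction for dCTCF turned when only the main chromosome arms (2L, 2R, 3L, 3R, 4 and X) were counted, where the mitotic list held 2237 peaks and the interphase list 2882. The remaining mitotic dCTCF peaks lay mainly on Uextra, the collection of sequence not placed on any chromosome, which held 55.6% (54.3 to 56.8%) of that list and 22.7% (21.4 to 24.0%) of the interphase list. For CP190 the Uextra share was 6.84% in interphase and 28.8% in mitosis, and for BEAF it was 23.7% and 24.4%. Su(Hw) had 39.2% of its mitotic peaks there. Median peak widths were 586.5 bp for CP190 in interphase and 561 bp in mitosis, 472 and 540 bp for BEAF, and 581 and 871 bp for dCTCF. The Su(Hw) median was 817 bp.

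**Figure D1:**
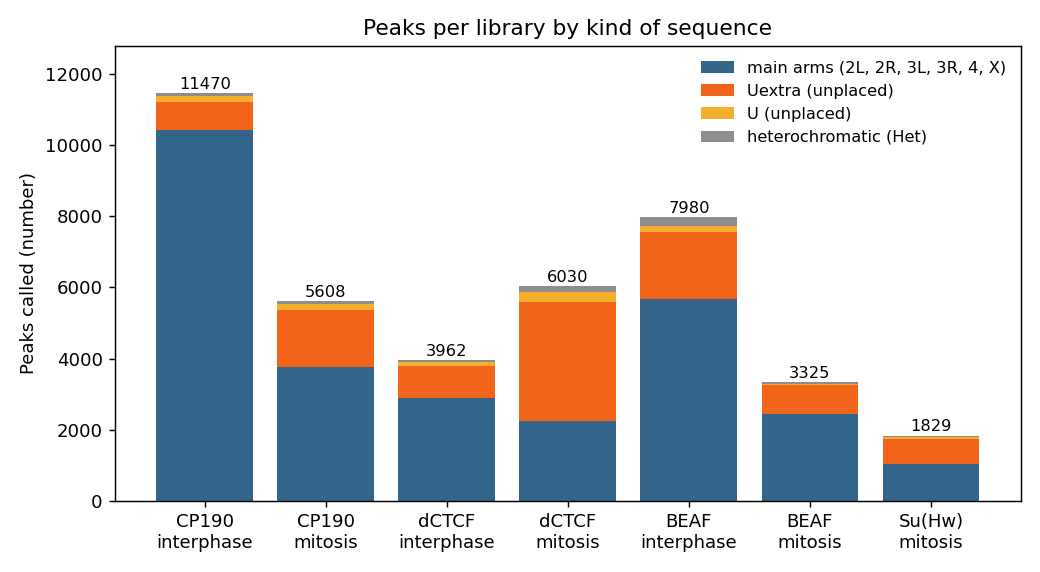
Number of peaks called in each of the 7 libraries, stacked by the kind of sequence they lie on, with the total above each bar. The mitotic dCTCF bar is the only one with more peaks on Uextra (3351) than on the main arms (2237).

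BEAF in mitosis was found almost entirely at sites that it also occupied in interphase. Of the 3325 mitotic BEAF peaks, 90.8% (89.7 to 91.7%) overlapped an interphase BEAF peak, and on the main arms 2411 of 2432 did (99.1%, 98.7 to 99.4%). In the opposite direction, 3035 of the 7980 interphase peaks were retained (38.0%, 37.0 to 39.1%), against a median of 2.36% when the interphase peaks were placed at random within their chromosomes. Retention was higher at higher interphase peak scores. Within the main arms it was 1.93% (1.28 to 2.91%) in the lowest quintile of scores, 18.9% (16.8 to 21.3%) in the third quintile and 99.8% (99.4 to 100%) in the highest. Retained BEAF peaks had a median score of 1826.07 and peaks called in interphase alone a median of 124.63. Among the highest scoring retained peaks, the site at X 9552659 to 9553293 was called in 6 of the 7 lists, all except Su(Hw), with a BEAF score of 3233.06 in interphase and 2082.9 in mitosis. The retained sites at 2L 1169545 to 1170676 and 3L 8527527 to 8528353 had mitotic BEAF scores of 2311.5 and 1311.16. The interphase peaks without a mitotic call had lower scores. The highest scoring was at X 15604434 to 15605335 (2126.6), where CP190, dCTCF and Su(Hw) were called in mitosis, and the next was at 2R 3843165 to 3843870 (1956.37), where no protein was called in mitosis. The 21 mitotic BEAF peaks on the main arms without an interphase call were weak. The highest scoring of them, at 3L 22887317 to 22887720, had a score of 107.24 and lay in a region called for CP190, dCTCF and Su(Hw), where an interphase BEAF peak overlapped the same interphase CP190 peak but not this BEAF peak. Chromosome X had the highest retained share of the arms at 47.6% (44.8 to 50.5%), and the other large arms lay between 40.1 and 41.5%. With the 3325 highest scoring peaks of both lists, the retained share was 75.9%.

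CP190 was retained at a minority of its interphase sites, and the retained share was higher in each successive quintile of scores. In all, 3895 of 11470 interphase peaks overlapped a mitotic peak (34.0%, 33.1 to 34.8%), against a median of 4.21% for random placement. Main-arm retention ranged from 13.2% (11.8 to 14.7%) in the lowest score quintile through 32.8% (30.9 to 34.9%) in the fourth to 71.0% (69.0 to 72.9%) in the highest. Of the 5608 mitotic peaks, 70.1% (68.9 to 71.3%) had an interphase call, and on the main arms 88.2% (87.1 to 89.2%) did. Strong CP190 sites went both ways. The site at 2L 9567323 to 9568039, which also carried dCTCF in interphase with a score of 2738.87, had a CP190 score of 3188.2 in interphase and 758.32 in mitosis. The site at 2L 900813 to 902093, which had a Su(Hw) peak in mitosis with a score of 817.93, had CP190 scores of 3189.39 and 496.28. By contrast, the interphase CP190 peaks at 2R 12495859 to 12497354 (3224.03) and 2R 13379973 to 13381626 (3166.84) had no call in any other list, and that at 3R 22781283 to 22782531 (3121.37) lay at an interphase dCTCF peak with a score of 3100 but had no mitotic call of any protein. The highest scoring CP190 peak called in mitosis alone was at 2R 18565442 to 18566294 with a score of 492.47, where Su(Hw) was also called. Of the 8 highest scoring peaks of this class, 4 overlapped a mitotic Su(Hw) peak and 4 an interphase BEAF peak. Over all mitotic CP190 peaks on the main arms these shares were 17.0% and 50.1%. Most of those peaks also had an interphase CP190 call. Of the 443 called in mitosis alone, 17.4% (14.1 to 21.2%) overlapped an interphase dCTCF or BEAF peak. A peak of another mitotic list was overlapped by 34.1% (29.8 to 38.6%) of them.

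Most mitotic dCTCF peaks lay away from the interphase dCTCF sites, and dCTCF retention on the main arms was not higher in each successive score quintile, as it was for BEAF and CP190. Of the 6030 mitotic dCTCF peaks, 28.0% (26.8 to 29.1%) overlapped an interphase dCTCF peak, and on the main arms 40.5% (38.5 to 42.5%) did. The dCTCF list is the shortest of the 3 interphase lists. Against as many of the highest scoring interphase CP190 peaks (2882) the mitotic CP190 share was 49.7% (48.1 to 51.3%) in place of 88.2%. The 3759 mitotic CP190 peaks outnumber these interphase peaks, which holds that share down. Of the 3962 interphase peaks, 1785 were retained (45.1%, 43.5 to 46.6%), against a median of 6.52% for random placement. The retained share was 80.0% (77.2 to 82.5%) for the 899 peaks on Uextra and 33.8% (32.1 to 35.5%) on the main arms, where it was between 31.5 and 38.3% on the large arms and X and 1 of 26 peaks was retained on chromosome 4. By quintile of interphase scores there, retention was 41.8% (37.8 to 45.8%) in the lowest, 11.1% (8.80 to 13.9%) in the fourth and 56.9% (52.9 to 60.9%) in the highest. Over the whole list the shares from the lowest to the highest quintile were 50.9, 48.7, 31.7, 43.7 and 50.3%. The lowest quintile exceeded the fourth by 30.7 percentage points (25.8 to 35.3), while the same difference was -19.6 points for CP190 and -84.8 points for BEAF. With a reciprocal overlap of 50% required, the overall retained share was 29.8% and the excess of the lowest quintile 12.6 points, and over the whole lists that excess was 7.26 points.

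**Figure D2:**
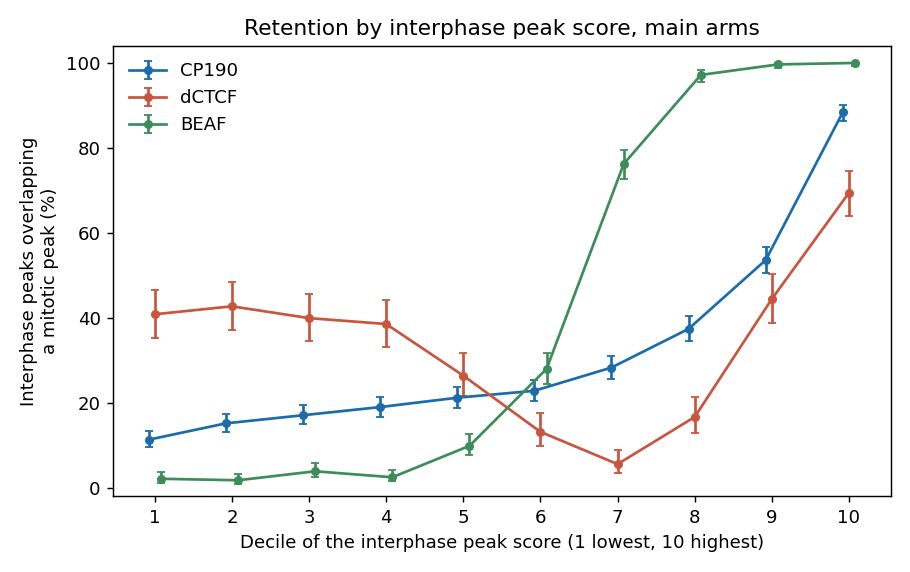
Share of interphase peaks on the main arms that overlapped a mitotic peak of the same protein, by decile of the interphase peak score. Bars are 95% Wilson intervals. BEAF goes from 2.11% in the lowest decile to 100% in the highest and CP190 from 11.3% to 88.4%, while dCTCF goes from 40.8% to 5.56% in the seventh decile and to 69.4% in the highest. Tied dCTCF scores of 3100 were split by file order between the last 2 deciles, at 44.4 and 69.4%, so only their joint share, 56.9%, is free of that order.

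Most of the strongest interphase dCTCF sites had CP190 in mitosis, both with and without a mitotic dCTCF call. In the highest quintile of interphase dCTCF scores on the main arms, CP190 was called in mitosis at 76.2% (71.3 to 80.5%) of the 328 retained peaks and at 72.6% (66.7 to 77.8%) of the 248 peaks without a mitotic dCTCF call, shares whose intervals overlapped. The intervals did not overlap everywhere: in the lowest quintile CP190 was at 70 of 241 retained peaks (23.7 to 35.1%) and 147 of 336 others (38.5 to 49.1%), and over all scores the shares were 49.7% (46.6 to 52.9%) and 40.8% (38.6 to 43.0%). This comparison was made after the named peaks had been seen. Of the 8 highest scoring dCTCF peaks called in interphase alone, 7 had a mitotic CP190 peak. They included 3R 8047638 to 8048692, with a dCTCF score of 3219.64 and a mitotic CP190 score of 807.07, and 3R 15316574 to 15317136, with scores of 3233.06 and 387.24. The exception was 2R 15520147 to 15520833. Retained examples were X 20395406 to 20396598, called in every list except Su(Hw), with dCTCF scores of 3196.89 in interphase and 731.86 in mitosis, and 3L 11241267 to 11241808, with 3206.98 and 689.46. The 8 highest scoring dCTCF peaks called in mitosis alone were broad regions. They included 3R 24618408 to 24623863 with a width of 5456 bp and a score of 1859.49, and 3L 17723873 to 17731484 with 7612 bp and 1515.09. Of these 8 regions, 4 overlapped a mitotic Su(Hw) peak and 5 an interphase CP190 peak. Over all mitotic dCTCF peaks on the main arms, with a median width of 896 bp, the shares were 6.62% and 72.2%. Of the 1331 called in mitosis alone, 77.1% overlapped an interphase CP190 or BEAF peak and 46.6% a peak of another mitotic list. Wider regions overlap other lists more readily, and the named regions were not compared with others of their width.

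Mitotic dCTCF peaks on the main arms lay more often at interphase BEAF sites than at interphase dCTCF sites. The difference was within the intervals when equal numbers of the highest scoring interphase peaks were used. With the full interphase lists the shares were 66.1% (64.1 to 68.0%) at BEAF sites, 72.2% (70.3 to 74.0%) at CP190 sites and 40.5% at dCTCF sites. Against the 2882 highest scoring interphase peaks per protein the shares were 41.7% (39.6 to 43.7%) for BEAF, 26.8% (25.0 to 28.7%) for CP190 and 40.5% (38.5 to 42.5%) for dCTCF. For dCTCF these are the whole main-arm list, and for BEAF and CP190 the stronger part of 5681 and 10431 peaks. The sets are thus equal in number but not in the range of scores. Against the same number of interphase peaks, mitotic BEAF peaks lay at interphase BEAF sites in 96.0% of cases. Mitotic CP190 peaks lay at interphase CP190 sites in 49.7%. The mitotic lists were not cut, and the 3759 mitotic CP190 peaks outnumber 2882 interphase peaks, so list length holds the CP190 share down. Most of the strongest mitotic dCTCF peaks lay at interphase dCTCF sites. The share there was 22.3% (18.7 to 26.4%) in the lowest quintile of mitotic scores and 74.5% (70.3 to 78.3%) in the highest, whereas the share at BEAF sites was 68.5% in both. Interphase dCTCF peaks that carried BEAF were retained in 48.2% (45.6 to 50.8%) of 1399 cases and those without it in 20.2% (18.2 to 22.3%) of 1483. Within the lowest score quintile these shares were 47.3% and 29.7%, and within the highest they were 65.6% and 49.7%. The peaks with BEAF were not uniform. Retention was 80.8% (73.9 to 86.2%) with BEAF only, 44.1% with CP190 and BEAF, 23.3% with CP190 only and 14.5% with neither. Within the lowest quintile these shares were 77.3%, 40.3% (35.1 to 45.8%), 24.4% and 39.7% (28.5 to 52.0%).

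**Figure D3:**
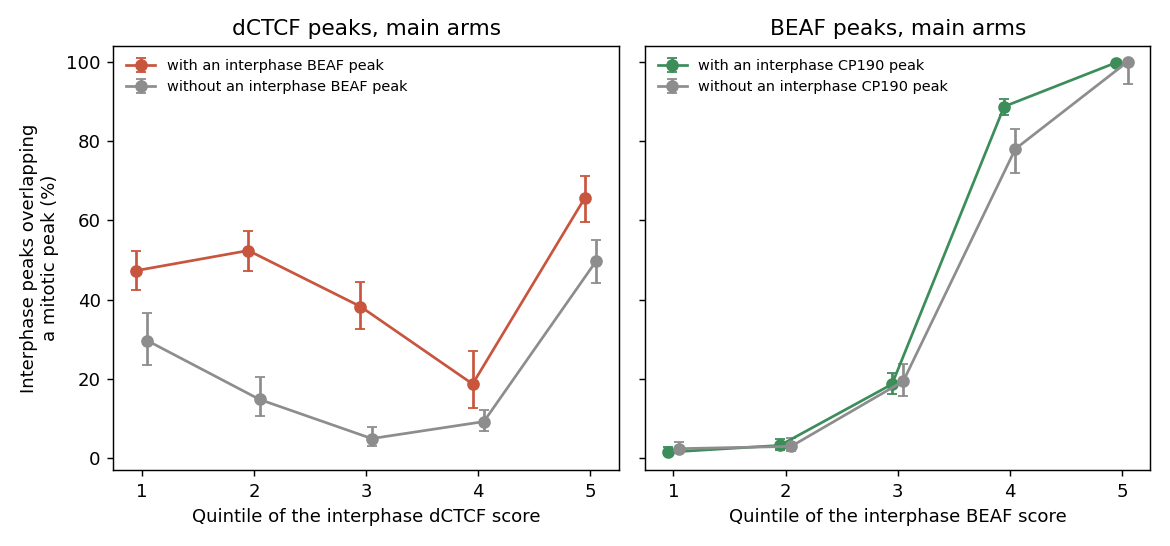
Share of interphase peaks on the main arms that overlapped a mitotic peak of the same protein, by quintile of the interphase score (1 lowest). The left panel splits dCTCF peaks by an interphase BEAF peak and the right panel BEAF peaks by an interphase CP190 peak. Bars are 95% Wilson intervals. dCTCF peaks with BEAF lie above those without it in each quintile, and the BEAF curves separate in the fourth quintile, at 88.7% with CP190 and 78.0% without.

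The lists also allow the association of dCTCF and BEAF with CP190 to be compared between phases, and that of Su(Hw) to be given in mitosis. In interphase 69.4% (67.9 to 70.8%) of dCTCF peaks and 55.2% (54.1 to 56.3%) of BEAF peaks overlapped a CP190 peak. In mitosis the shares were 33.5% (32.3 to 34.7%) and 35.4% (33.8 to 37.1%), and 65.2% (63.0 to 67.4%) for Su(Hw). Random placement gave medians of 8.88% and 8.30% in interphase and of 6.82%, 4.36% and 5.96% in mitosis. Counted on the main arms, the shares in interphase and mitosis were 76.2 and 35.0% for dCTCF and 72.6 and 42.7% for BEAF, while Su(Hw) stood at 60.5%. The CP190 list was itself shorter in mitosis, so these shares compare lists of different lengths. Equal numbers of the highest scoring peaks within each pair of lists did not remove this, since the number differed between pairs. The shares were then 42.8% of 3962 dCTCF peaks in interphase and 34.1% of 5608 in mitosis, 45.6% of 7980 and 25.6% of 3325 BEAF peaks, and 29.2% of 1829 Su(Hw) peaks, so they rank neither phases nor proteins. With a reciprocal overlap of 50%, mitotic dCTCF stood at 21.2%.

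On the main arms, 60.5% (57.5 to 63.5%) of mitotic Su(Hw) peaks overlapped mitotic CP190, against 42.7% for BEAF and 35.0% for dCTCF. Random placement gave medians of 5.18, 3.95 and 5.63%. This order depended on the measure. Over the whole lists with equal numbers of highest scoring peaks, the shares were 29.2, 25.6 and 34.1%. Counted from the mitotic CP190 peaks on the main arms, 17.0% overlapped Su(Hw), 28.1% BEAF and 21.8% dCTCF. The overlap of Su(Hw) with mitotic dCTCF was 14.6% (12.5 to 16.8%) and 123 of its 1024 peaks overlapped mitotic BEAF. The share of Su(Hw) peaks with mitotic CP190 was 42.0% (35.4 to 48.8%) in the lowest quintile of Su(Hw) scores and 85.8% (80.3 to 89.9%) in the highest. Of all Su(Hw) peaks on the main arms, 74.8% overlapped interphase CP190, 27.2% interphase BEAF and 19.2% interphase dCTCF. The 8 highest scoring Su(Hw) peaks all had CP190 in both phases and BEAF in interphase, and 6 had dCTCF in interphase. In the highest quintile of Su(Hw) scores, 94.1% overlapped interphase CP190, 38.7% interphase BEAF and 33.8% interphase dCTCF. Wider regions overlap other lists more readily, and the main-arm median width was 842.5 bp. These 8 peaks were 1958 to 4075 bp wide, except X 18133241 to 18134072, of 832 bp. Among them, 3R 10130315 to 10134282 had a Su(Hw) score of 3100 and a mitotic CP190 score of 3100, and X 18133241 to 18134072 had a Su(Hw) score of 2751.2 and a mitotic dCTCF score of 1650.24. The peak at 2R 10657209 to 10660113, with a score of 3100, lay in a region called in all 7 lists. The median Su(Hw) score was 78.12, and 33.1% of the Su(Hw) peaks had a score of at least 100.

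**Figure D4:**
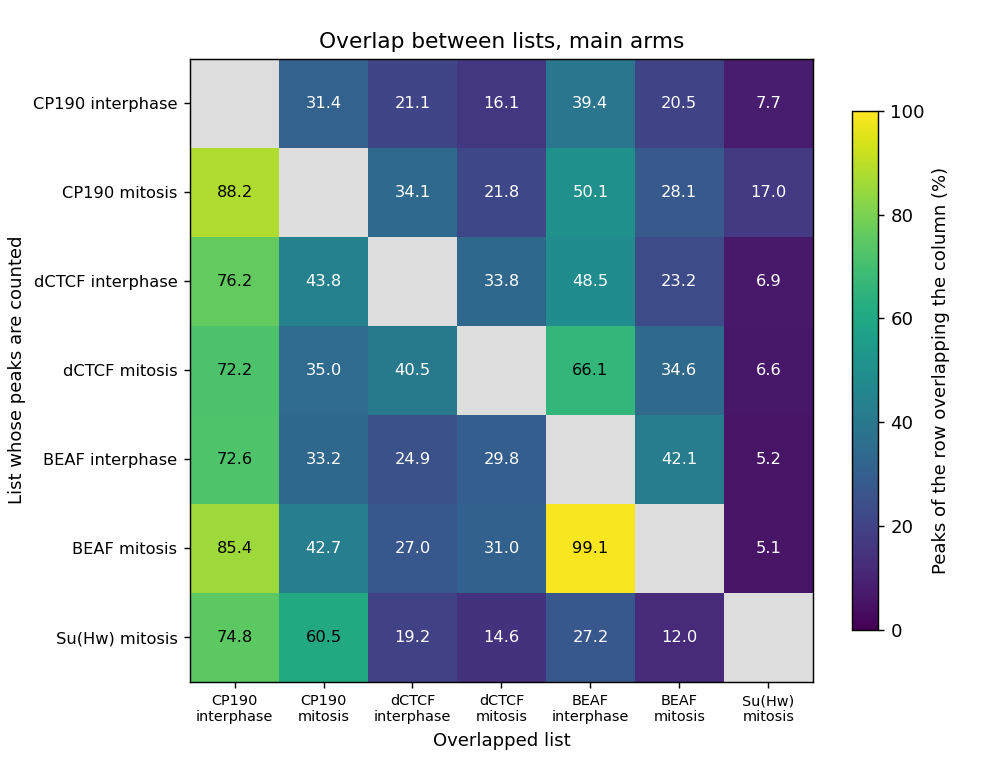
Share of the peaks of each list (rows) that overlap a peak of each other list (columns) by at least 1 bp on the main arms, in percent. Mitotic BEAF peaks lie at interphase BEAF sites in 99.1% of cases, mitotic CP190 peaks at interphase CP190 sites in 88.2%, and mitotic dCTCF peaks at interphase dCTCF sites in 40.5%.

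CP190 peaks that coincided with another insulator protein in interphase were retained more often than CP190 peaks alone over all scores. This did not hold in the lowest and second score quintiles, nor in the third for peaks with dCTCF only. Of the main-arm peaks, 19.7% (18.7 to 20.8%) of the 5367 CP190 peaks without dCTCF or BEAF were retained, 33.9% (32.2 to 35.7%) of the 2867 with BEAF only, 42.0% (38.9 to 45.1%) of the 953 with dCTCF only, and 68.2% (65.5 to 70.7%) of the 1244 with both. The peaks with both also had higher scores, with a median of 1608.82 against 187.17 for peaks with neither. Within the highest quintile of CP190 scores the retained shares were 41.8% (37.9 to 45.8%) with neither, 74.4% (69.9 to 78.5%) with dCTCF only, 79.5% with BEAF only and 88.5% (86.0 to 90.6%) with both. Median scores still differed within that quintile, at 1806.93, 2478.41, 1815.85 and 2910.04 in the same order. Within the lowest quintile the retained shares were 13.8% (12.1 to 15.6%), 4.69% (2.17 to 9.85%), 13.9% and 13.9%. Within the second they were 18.8% (16.7 to 21.0%), 7.09% (3.77 to 12.9%), 18.8% and 17.2%. Within the third they were 18.6% (16.4 to 21.0%), 18.3% (12.5 to 25.9%), 26.5% and 29.9%, and within the fourth 17.6%, 37.6%, 43.9% and 51.8%.

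Whether CP190 in interphase went with retention of its partners was examined for BEAF and dCTCF. BEAF peaks with CP190 were retained in 48.5% of 4404 cases and those without in 25.1% of 3576, a difference of 23.4 percentage points (Newcombe interval 21.3 to 25.4). The main-arm difference was 29.2 points (26.6 to 31.7), but BEAF peaks with CP190 had a median score of 598.78 and those without it 146.11. Within score quintiles on the main arms the difference was -0.889, 0.246 and -0.743 points in the lowest, the second and the third quintile, with intervals that included 0, then 10.7 points (5.20 to 17.0) in the fourth and -0.187 points in the highest. Over the whole list the differences from the lowest to the highest quintile were -5.79, -12.3, -21.7, 0.787 and 4.66 points, so the overall direction was not seen within the lower quintiles. With equal numbers of highest scoring peaks in the lists the overall difference was 6.24 points. For dCTCF the difference was -3.45 points (-6.82 to -0.0906) over the whole lists and 5.53 points on the main arms. Its direction depended on the processing, since over the whole lists it was also 17.6 points with a reciprocal overlap of 50%, 12.1 with a score of at least 100 and 3.63 with 400 bp around each midpoint. It showed no steady trend with score: from the lowest to the highest quintile it was -24.2, -16.3, 14.0, 0.0809 and -23.7 points on the main arms, where the highest quintile held 15 peaks without CP190 and had an interval of -37.3 to 1.84. Over the whole list it was -33.8, -31.8, 6.84, 42.6 and 6.71 points.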

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

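All tests in this part were chosen after the results they bear on had been seen. For the BEAF peaks this includes the choice of score bins, since the test for a remaining CP190 effect was first made over 20 bins and was changed to 5 of them once that value was known. Each group is 1 library, so no difference between proteins was tested and no regrouping of samples was possible.

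The number of dCTCF peaks was 2068 higher in mitosis than in interphase, while the number of CP190 peaks fell by 5862 and that of BEAF peaks fell by 4655; this opposite direction drew attention to it, and the difference between proteins was not tested. On the main arms the dCTCF difference was -645 peaks, so unplaced and heterochromatic sequence held the whole excess. The Poisson interval of that difference, -785 to -505, covers counting error only and no variation between libraries. A rise in the Uextra share with every antibody was not seen. The BEAF share changed by 0.762 points (-0.952 to 2.51) against 22.0 for CP190 and 32.9 for dCTCF. A share depends on the other peaks of its list, so this cannot exclude a background common to all mitotic libraries. Of the mitotic dCTCF peaks on Uextra, 62.6% (61.0 to 64.2%) overlapped a peak of another protein, which is consistent with sites that several antibodies bring down but does not set Uextra apart, since the share was 85.5% on the main arms. The treatment of reads with several matches, the control library, the antibody mixture, the antibody present from sorting and a change of dCTCF binding in mitosis stay open and were not tested.

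Interphase dCTCF peaks of low score on the main arms were retained more often than those of middle score, by 30.7 points (25.8 to 35.3) between the lowest and the fourth quintile, whereas CP190 and BEAF went the other way. Lower depth of the mitotic library alone is argued against by its strongest quintile of peaks, 25.5% (21.7 to 29.7%) of which had no interphase dCTCF peak, against 0.266% for CP190, or 12.8% (9.97 to 16.2%) with equal numbers of mitotic and interphase peaks. The 25.5% was not recomputed without peaks of at least 3000 bp, so how far it rests on broad regions is not known. The mitotic dCTCF list had 144 such peaks on the main arms and the interphase list 1. Signal at BEAF sites as the whole cause is argued against by dCTCF peaks with no BEAF peak, where the lowest quintile still exceeded the fourth by 20.4 points (13.6 to 27.8). A mix-up with the CP190 antibody is argued against by the share at interphase CP190 sites, which differed between its strongest and weakest quintiles by -1.18 points (-6.94 to 4.60), or 7.36 without peaks of at least 3000 bp, against 26.3 (23.2 to 29.6) in the mitotic CP190 library. A mix-up with the BEAF or Su(Hw) antibody is argued against by its 447 strongest peaks, which lay at interphase dCTCF sites more often than as many BEAF peaks by 38.3 points (32.0 to 44.0), though not more often than CP190 peaks beyond the interval (1.34 points, -4.42 to 7.09). An antibody used for none of these lists stays open, since the rise of 52.2 points (46.3 to 57.4) with score at dCTCF sites was near the 44.9 of the CP190 library, as do the hypotheses of a mixture of dCTCF signal with signal shared by open chromatin and of a loss of dCTCF from middle scoring sites.

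Interphase BEAF peaks with CP190 on the main arms were retained more often than those without, by 29.2 points. Averaged within 20 bins of the BEAF score the difference was 0.683 points (-0.973 to 2.34), below 14.6 points, so most of it is consistent with higher BEAF scores at CP190 sites. Many of these bins are near 0 or 100% retention and cannot show a difference, and in the 5 bins between 10 and 90% it was 2.44 points (-2.51 to 7.39). This does not show that CP190 has no effect, since those bins were chosen after the first value was known and the fourth score quintile, a coarser bin, had a difference of 10.7 points (5.20 to 17.0). A higher BEAF score may itself come from joint occupancy, which these lists cannot separate.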

How the results depend on the processing

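All percentages here are shares of peaks, given in the order CP190, dCTCF and BEAF for retained interphase peaks and for mitotic peaks with an interphase call, then in the order interphase dCTCF, interphase BEAF, mitotic dCTCF, mitotic BEAF and Su(Hw) for overlap with CP190. With a reciprocal overlap of 50% the retained shares were 28.1, 29.8 and 34.2%, the mitotic shares 57.5, 19.6 and 82.0%, and the CP190 overlaps 53.0, 38.4, 21.2, 29.7 and 57.5%. With a score of at least 100 they were 27.5, 35.7 and 44.5%, 80.8, 26.6 and 90.8%, and 67.6, 57.7, 25.0, 25.6 and 66.0%. With equal numbers of highest scoring peaks they were 48.2, 38.4 and 75.9%, 49.8, 35.9 and 77.4%, and 42.8, 45.6, 34.1, 25.6 and 29.2%. With 400 bp around each midpoint they were 32.3, 39.0 and 37.2%, 66.4, 25.5 and 89.5%, and 64.5, 52.3, 29.1, 33.8 and 62.4%. On the main arms they were 31.4, 33.8 and 42.1%, 88.2, 40.5 and 99.1%, and 76.2, 72.6, 35.0, 42.7 and 60.5%. The order of the retained shares therefore changed with the setting, and BEAF had the highest except over the whole lists and with 400 bp around each midpoint, where dCTCF did. The BEAF difference with minus without CP190 stayed positive, at 30.4 points with the reciprocal overlap, 19.2 with the score minimum, 6.24 with equal numbers, 22.8 with 400 bp and 29.2 on the main arms. The dCTCF difference of -3.45 points reversed to 17.6, 12.1, 3.63 and 5.53 points with the reciprocal overlap, the score minimum, 400 bp and the main arms, and was -15.9 points with equal numbers; the cause was not tested. In alternatives added after the data were seen, the change in the number of dCTCF peaks reversed to -645 on the main arms and -768 with a score of at least 100 there, and was 893 with that score minimum over the whole list, while the BEAF change was -2751 with the score minimum and -2364 with it on the main arms. The CP190 change stayed between -5862 and -6672. The excess of the lowest over the fourth dCTCF score quintile was 7.26 points over the whole lists, 12.6 with the reciprocal overlap and 24.2 with 400 bp. No group has a replicate to leave out. Both phases of a protein form a pair, but a fit over the 3 pairs would treat different antibodies as replicates and was not made. Other start site distances, gene list distances and motif windows were not run because no annotation or genome of the release of the files was used here. Depth limits every share, since a shallower mitotic library loses weak sites, and the lists hold no read numbers to correct for it.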

Other observations

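All counts in this part, and the sites named, were chosen after the data were seen. On the main arms, 26 interphase CP190 peaks overlapped a peak in all 6 other lists. They included 2L 20120219 to 20121631, 3L 22887192 to 22888603 and X 20630893 to 20632024, each with an interphase CP190 score of 3100. In mitosis 33 CP190 peaks overlapped dCTCF, BEAF and Su(Hw) peaks.

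Broad peaks, of at least 3000 bp, were most frequent in the mitotic dCTCF list, with 144 on the main arms (6.44% of its peaks there), and in the Su(Hw) list, with 42 (4.10%). The interphase dCTCF list had 1, the interphase and mitotic CP190 lists had 30 and 31, and the BEAF lists had 19 and 2. Of the 144 mitotic dCTCF regions, 139 overlapped a peak of at least 1 other list and 66 overlapped peaks of 3 or more, and of the 42 Su(Hw) regions 36 overlapped peaks of 3 or more other lists.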
